A study of Mus musculus with 8 samples.

How the data were processed

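Gene expression was measured on Affymetrix Mouse Gene 2.0 ST arrays in neutrophils that had migrated into air pouches of mice injected with lipopolysaccharide (LPS). Per the series' design text, each array held RNA from neutrophils pooled from 5 mice and purified by negative selection, with 98% of cells positive for the neutrophil marker Ly6G. Per the labels' protocols, 100 ng of total RNA was used per array, and RNA with an integrity number under 7 was not accepted. The design text and the labels' protocols name different RNA isolation reagents and different labelling kits, and which were used could not be settled here.

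The values are the deposited log2 probe set intensities, which the authors made by background subtraction and normalization with the Robust Multiarray Analysis (RMA) method in Affymetrix Expression Console, per the design text. The software version, and whether further arrays were normalized together with these, are not given in the sources used here. Array medians lay between 5.41 and 5.48 and the quantiles of the 8 arrays were alike, so no further scaling was applied. The genome build behind the probe set annotation is not given in the sources used here, so no coordinates are printed. Gene names were brought to current symbols by gene identifier with the RefSeq annotation of GRCm38.p6, which also gave chromosome numbers and the order of genes along a chromosome.

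Groups were taken from the sample titles and the genotype labels. The source field of every sample names another genotype than its title and genotype label do, and the Arf6 level of each array was used to check the choice. The conditional knockout (cKO, homozygous for the floxed Arf6 allele and for Cre) had 3 arrays, the flox control (floxed allele without Cre) had 3, and the Cre control (Cre without the floxed allele) had 2. The design text states 3 pools for each genotype. The remaining Cre control pool was not analysed here.

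Of 34472 probe sets, 23521 carried 1 gene symbol. Of those, the 14002 with a value above the median of all values (5.45, log2) in at least 2 arrays were tested, covering 13296 genes. Probe sets with several symbols (1814) or none (9137) were left out of the gene comparisons. Probe sets were compared with limma 3.58.1 in R 4.3.3 in a single fit of 3 groups with a moderated variance (5 residual and 4.69 prior degrees of freedom). Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over all probe sets tested, and the threshold was 0.05. The cKO was compared with the mean of both control groups, with each control group alone, and the control groups with each other. Errors of log2 fold changes are standard errors (SE) of this fit. The SE of a list median was instead taken over the genes of the list and holds no spread between pools. Where groups have no overlap, the share of probe sets that chance would give is stated beside the count.

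The design, the gene comparisons and 38 gene lists were fixed before the data were examined, as were the alternatives except those named below as later choices. Set tests of the lists were fixed for the cKO against both controls and for the controls against each other. Those of the cKO against each control alone were not part of that plan. The lists covered carbon metabolism, neutrophil granules and functions, LPS and interferon responses, ARF6 biology, stress, and markers of other cell types. The 36 lists with at least 5 tested genes were tested with limma's camera, with 1 probe set per gene and an inter-gene correlation preset to 0.01. The test was repeated with a correlation estimated for each list and with limma's fry, and p was adjusted over the 36 lists. An exact permutation test over the 56 splits of 3 against 5 arrays was run on each list's mean level. The genes named were Arf6 and, in each comparison, up to 12 genes with the highest and 12 with the lowest fold change past the threshold whose arrays did not overlap, leaving out predicted, microRNA and small nucleolar RNA genes. Where fewer than 5 genes passed, the 6 higher and 6 lower genes with the smallest p were named instead, and list members were named by smallest p.

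The pipeline was tested on simulated data with 14002 probe sets, of which 200 were changed, in 20 simulations. At a log2 change of 1 it recovered 85.7% of changed probe sets for the cKO against both controls, 78.1% against the flox control, 69.2% against the Cre control and 69.3% between the controls, and 4.32% to 4.61% of calls were false. At a log2 change of 0.5 these shares were 31.6%, 23.5%, 13.8% and 13.6%. A list planted with a log2 change of -0.25 was found in 20 of 20 simulations, in which genes varied independently. The alternatives tried were other filters, other scalings, other variance models, array weights, other fits and leaving out each array in turn. The number of arrays limits the precision of every value.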

Results

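Messenger RNA levels were measured in neutrophils that had entered LPS-injected air pouches of mice, with and without the small GTPase Arf6, which acts in membrane traffic and at the actin cytoskeleton. The series is titled as a study of how Arf6 relates to glycolytic metabolism and effector functions of these cells. The 8 arrays comprised 3 cKO pools, 3 flox control pools and 2 Cre control pools, each from 5 mice. Array medians (log2) were 5.46, 5.41 and 5.46 in the flox controls, 5.42, 5.44 and 5.45 in the cKO, and 5.48 and 5.47 in the Cre controls. Correlations across probe sets between any 2 arrays ranged from 0.977 to 0.992, genes not being independent replicates. The first flox control pool had the lowest mean correlation with the other arrays (0.981). Sex-linked transcripts showed that 2 pools differed from the rest. Xist, expressed from the inactive X chromosome, read 5.46 in flox control replicate 1 and at least 7.84 in the other arrays, and the Y-linked gene Eif2s3y read 4.08 in cKO replicate 1 and at least 8.66 in the others.

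Arf6 itself was lower in the cKO. Its mean level (log2 ± SD) was 6.25 ± 0.22 in the cKO (n = 3), 8.02 ± 0.30 in the flox control (n = 3) and 7.82 ± 0.05 in the Cre control (n = 2). Arf6 (gene identifier 11845, chromosome 12, probe set 17275925) fell 3.19-fold against both controls, a log2 fold change of -1.67 (SE 0.15, 95% interval -2.01 to -1.33, adjusted p = 0.0122), to 31.3% of the control signal. The cKO reading lay below the 75th percentile of all values (6.64). This share is one of array signal, and how much transcript remained cannot be read from it. Against the flox control Arf6 fell 3.42-fold (log2 -1.77, SE 0.17, adjusted p = 0.0162) and against the Cre control 2.98-fold (log2 -1.57, SE 0.19, adjusted p = 0.0283). The control groups differed by -0.20 (SE 0.19, adjusted p = 0.68), Cre control minus flox control. The 3 cKO arrays lay between 6.06 and 6.49 and the 5 control arrays between 7.68 and 8.20, so the levels followed the titles and genotype labels. A second Arf6 probe set (17281565) read 6.29 in the cKO, 6.55 in the flox control and 6.33 in the Cre control, and its difference from both controls (-0.15, SE 0.15, adjusted p = 0.816) did not pass. Which part of the gene either probe set reads is not given in the sources used here. The call against both controls was lost without flox control replicate 2 (log2 -1.63, adjusted p = 0.0773), Cre control replicate 1 (-1.69, 0.154) or Cre control replicate 2 (-1.66, 0.182), and without the 2 pools with distinct sex-linked transcripts (-1.75, 0.0791). Over the alternatives adjusted p for Arf6 ranged from 0.00201 to 0.182 against both controls, up to 0.193 against the flox control and up to 0.407 against the Cre control. The call against each control alone was lost in these settings too and without cKO replicate 1, and that against the flox control also without flox control replicate 1 and in a fit of the compared groups alone.

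**Figure D1:**
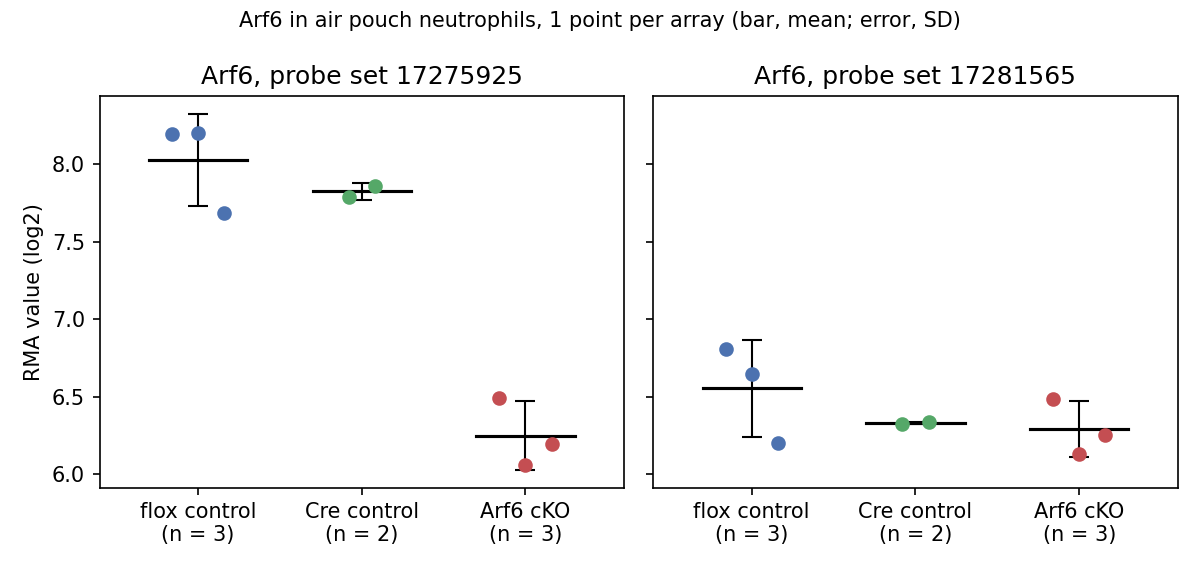
Level of the 2 Arf6 probe sets (log2, vertical axis) in each of the 8 arrays by group, with group means as horizontal lines and SD as error bars. Probe set 17275925 lies between 6.06 and 6.49 in the 3 cKO arrays and between 7.68 and 8.20 in the 5 control arrays, while the other probe set overlaps between groups.

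The comparison of the cKO with both controls asked how the cKO differs from the mean of the 2 control groups. Differences between the control lines enter that mean, so their background is not removed. Arf6 was the single gene past the threshold among 13296 genes. Genes of the LPS and NF-kB response, a list of cytokines, chemokines and their regulators, were lower as a group, with 40 of 49 tested members lower and a median log2 fold change of -0.27 (n = 3 against 5). The lowest were Il23a, the p19 subunit of interleukin 23 (-1.38, SE 0.28), Tnip3, an inhibitor of NF-kB signalling (-0.99, SE 0.20), and Tnfsf9, the ligand of 4-1BB (-0.93, SE 0.24). Other members low in the cKO were Il6 (-0.77, SE 0.22), the adhesion molecule Icam1 (-0.68, SE 0.20), the NF-kB subunit Relb (-0.48, SE 0.12) and the NF-kB brake Tnfaip3 (-0.43, SE 0.10). Some of the best known LPS-induced genes of neutrophils read alike in cKO and controls, with Il1b at 0.01 (SE 0.09), Cxcl2 at 0.06 (SE 0.10) and Ccl3 at -0.01 (SE 0.09). Il1b and Ccl3 averaged 13.98 and 13.99 over the arrays, where the highest reading of each array was 14.10 to 14.17. So close to the highest readings, a difference between groups may not be seen. Cxcl3 (0.39, SE 0.18), Vegfa (0.37, SE 0.15) and Osm (0.32, SE 0.14) lay above 0. None of the 49 genes passed over all genes tested, but 15 passed when p was adjusted over the list alone, all lower: Il23a, Tnip3, Tnfaip3, Relb, Tnfsf9, Zc3h12a, Tnip1, Il6, Icam1, Nfkb2, Il1a, Irak3, Nfkbib, Sod2 and Il10. By limma 26 of the 49 had an unadjusted p under 0.05. In 14 members all 3 cKO arrays lay below all 5 controls, where chance gives 1.79% of genes. The list fell in limma's camera test (adjusted p = 1.3e-11), with adjusted p = 0.883 with an estimated correlation. Its mean level was 10.9 ± 0.15 (SD, n = 3) in the cKO and 11.2 ± 0.06 (SD, n = 5) in the controls. Of the 56 splits of the arrays no other separated this mean as far as the real one, so the exact permutation p = 0.0179 (two-sided) was the smallest possible, and adjusted over 36 lists it was 0.643.

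**Figure D2:**
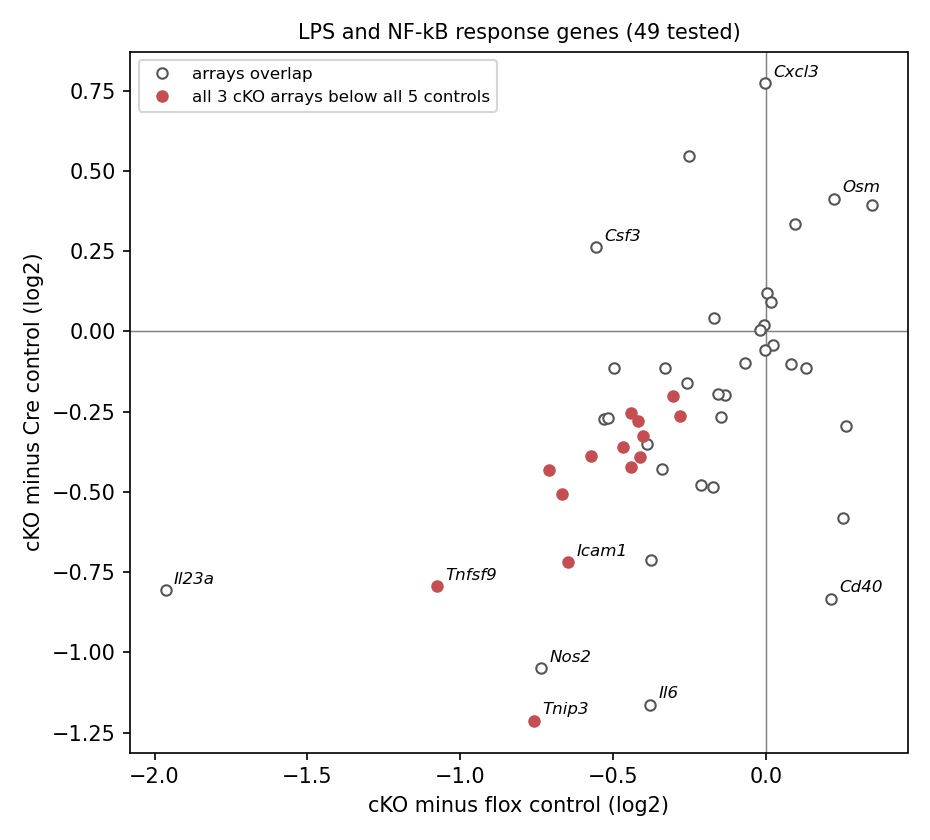
Log2 fold change of the tested members of the LPS and NF-kB response list in the cKO, against the flox control (horizontal axis) and against the Cre control (vertical axis), 1 point per gene, filled where all 3 cKO arrays lie below all 5 controls. Most members lie below 0 on both axes, with Il23a at -1.96 against the flox control and -0.81 against the Cre control.

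The other lists past the threshold against both controls were interferon-stimulated genes and apoptosis and survival genes, each lower. Of 40 tested interferon-stimulated genes 39 were lower (median -0.25, adjusted p = 1.3e-11, and 0.972 with an estimated correlation, and a median of -0.13 without cKO replicate 2), among them the antiviral GTPase Mx2 (-0.78, SE 0.25), the guanylate-binding protein Gbp5 (-0.46, SE 0.17) and the ubiquitin-like modifier Isg15 (-0.26, SE 0.10). None passed over all genes or when adjusted over the list alone, 5 had an unadjusted p under 0.05 by limma, and the list's exact permutation p was 0.232 (0.978 adjusted over 36 lists). Of 25 apoptosis and survival genes 20 were lower (median -0.14, adjusted p = 0.0142, and 0.883 with an estimated correlation, exact permutation p = 0.0357, and 0.643 adjusted over 36 lists), among them Bcl2a1a, a survival factor induced by NF-kB (-0.69, SE 0.19), and the death receptor Fas (-0.24, SE 0.10). None of the 25 passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05 by limma. The interferon list's mean level was 11.6 in cKO replicate 3, above all 3 flox controls. The apoptosis call was lost without flox control replicate 3, cKO replicate 1, cKO replicate 2 or the 2 pools with distinct sex-linked transcripts, and its median was -0.22 without cKO replicate 3, with adjusted p between 0.00635 and 0.0983 over its alternatives. With an estimated correlation no list passed in any of the 4 comparisons, and 52 of the 56 splits of the arrays gave at least 3 lists at the preset correlation, up to 12, so these list counts did not stand out from other groupings.

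Glycolysis genes, the subject of the series' title, did not shift in the cKO against both controls. Of 20 tested members 11 were higher and 9 lower (median 0.07, adjusted p = 0.924), none passed over all genes or adjusted over the list alone, and by limma 3 had an unadjusted p under 0.05. The lactate transporter Slc16a1 read -0.51 (SE 0.16), hexokinase Hk2 -0.48 (SE 0.18), the lactate exporter Slc16a3 0.44 (SE 0.19) and the glucose transporter Slc2a3 0.59 (SE 0.27). The list mean was 9.65 ± 0.08 (SD, n = 3) in the cKO and 9.63 ± 0.12 (SD, n = 5) in the controls (exact permutation p = 0.732, and 0.982 adjusted over 36 lists). Oxidative phosphorylation genes had a median of 0.01 (45 tested, adjusted p = 0.958) and genes of the neutrophil core a median of 0.03 (26 tested, adjusted p = 0.958).

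Outside the lists, the genes with the smallest p against both controls after Arf6 did not pass. On the lower side they were Cks2, a subunit of cell cycle kinases (-0.82, SE 0.11, adjusted p = 0.0696), the guanylate-binding protein Gbp8 (-1.21, SE 0.17), Lacc1, an enzyme of purine nucleoside metabolism (-1.52, SE 0.22), Pwp1 (-1.02, SE 0.18) and the antiviral deaminase Apobec3 (-0.90, SE 0.17). On the higher side they were Emilin2, an extracellular matrix glycoprotein (0.84, SE 0.13, adjusted p = 0.121), Cdk5rap1 (1.19, SE 0.19), Ndfip2 (0.90, SE 0.14), Bend4 (1.73, SE 0.29), the BMP receptor Bmpr1a (1.06, SE 0.18) and the peptide transporter Slc15a2 (1.02, SE 0.17). For Emilin2 and Gbp8 the cKO lay near the flox control, and the Cre control stood apart. Emilin2 averaged 12.06 in the cKO, 11.92 in the flox control and 10.52 in the Cre control, and Gbp8 5.53, 5.77 and 7.72. The cKO arrays of these 2 genes and of Bend4 overlapped those of the controls. By limma 1333 of 14002 probe sets had an unadjusted p under 0.05, where 700.1 would be due to chance. In 610 probe sets, or 4.36%, the 3 cKO arrays lay beyond all 5 controls, where chance gives 3.57%. The count of 1 gene became 0 without flox control replicate 2, Cre control replicate 1 or Cre control replicate 2 (704 to 1221 probe sets at unadjusted p under 0.05 in limma), 3 without cKO replicate 2 and 31 without cKO replicate 3.

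The comparison with the flox control asked how the cKO differs from mice with the same floxed allele and no Cre. Trim12a, a TRIM family gene on chromosome 7, was 22.9-fold higher in the cKO (log2 4.52, SE 0.51, adjusted p = 0.0162, n = 3 against 3), and Gart, an enzyme of purine synthesis, 2.02-fold higher (1.01, SE 0.13, adjusted p = 0.0367). Arf6 and Cks2 were lower, Cks2 2.08-fold (-1.06, SE 0.12, adjusted p = 0.0162). The Gart call was lost without any 1 of the 8 arrays (adjusted p up to 0.254, without flox control replicate 2) and in 11 of 17 other settings in all. The Trim12a call was lost in 9 of 18, among them the omission of any 1 array but cKO replicate 2 (up to 0.193, without flox control replicate 2). Cks2 lost its call without flox control replicate 1 or 2, cKO replicate 1 or either Cre control (up to 0.193). Both Trim12a and Gart also rose in the Cre control against the flox control. These comparisons share the flox control arrays, and simulated unchanged groups gave a mean overlap of 1.61 among as many top probe sets. In all, 6 probe sets of 4 genes passed, Cks2 with 3 probe sets of identical values, while another Cks2 probe set (-0.82, adjusted p = 0.251) and the other Gart probe sets (0.10 and 0.58) did not pass. The genes nearest to passing were Il23a (-1.96, SE 0.31, adjusted p = 0.132), the laminin chain Lamb3 (-0.69, SE 0.11), Zfp119b (-1.18, SE 0.19) and Ankrd22 (-1.04, SE 0.17) on the lower side. On the higher side they were Cdk5rap1 (1.43, SE 0.21, adjusted p = 0.104), Slc15a2 (1.21, SE 0.19), Stxbp5 (0.71, SE 0.11) and the costimulatory ligand Cd86 (0.87, SE 0.14).

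Of the lists, 5 passed against the flox control. The LPS and NF-kB list fell (38 of 49 lower, median -0.28, adjusted p = 1.24e-10, and 0.713 with an estimated correlation). Of its members 12 passed adjusted over the list alone and none over all genes, with 20 at an unadjusted p under 0.05 by limma. Interferon-stimulated genes (median -0.12, 34 of 40 lower, adjusted p = 0.0059) and specific and gelatinase granule genes (median -0.19, 19 of 24 lower, adjusted p = 0.0226) also fell, and both had adjusted p = 0.844 with an estimated correlation. Isg15 read -0.34 (SE 0.11) and the stefin Stfa2 -0.49 (SE 0.18). The interferon call was lost without flox control replicate 2 or cKO replicate 2, without the 2 pools with distinct sex-linked transcripts and with quantile scaling, with a median of -0.25 to 0.02 and adjusted p up to 0.912 over its alternatives, where leaving out cKO replicate 2 turned the direction (0.02), and it was -0.08 without flox control replicate 1 and -0.25 without cKO replicate 3. The granule call was lost in the same settings and without flox control replicate 1 (median -0.10) or cKO replicate 1 (adjusted p up to 0.44). Markers of other cell types moved with this comparison. T and NK cell markers rose (15 of 18 higher, median 0.29, adjusted p = 0.000917, and 0.551 with an estimated correlation), with the interleukin 7 receptor Il7r at 0.78 (SE 0.15), and so did dendritic cell and class II genes (12 of 16 higher, median 0.28, adjusted p = 0.0059, and 0.713 with an estimated correlation), with H2-Ab1 at 0.57 (SE 0.15), a call lost without the 2 sex-distinct pools (adjusted p = 0.1001), with a median of 0.12 without flox control replicate 1 and 0.16 with no filter on dim probe sets. Adjusted over the list alone, 1 T and NK marker and 2 dendritic cell genes passed, and none of the granule and interferon genes did. Glycolysis genes did not shift (10 higher and 10 lower, median -0.03, adjusted p = 0.222). By limma 1156 probe sets had an unadjusted p under 0.05. In 1713 probe sets, or 12.2%, the groups did not overlap, where chance gives 10%. The count of 6 probe sets became 0 without flox control replicate 1 or 2, cKO replicate 1, or either Cre control (749 to 1108 probe sets at unadjusted p under 0.05 in limma) and 11 without cKO replicate 2.

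The comparison with the Cre control asked how the cKO differs from mice that carry Cre without the floxed allele. Besides Arf6, Gbp8, an interferon-inducible guanylate-binding protein, fell 4.55-fold (log2 -2.19, SE 0.21, adjusted p = 0.00995, n = 3 against 2). Higher in the cKO were Emilin2, 2.91-fold (1.54, SE 0.16, adjusted p = 0.0133), Gpat3, an acyltransferase of triglyceride synthesis, 2.79-fold (1.48, SE 0.20), the chemokine-like peptide Prok2, 2.41-fold (1.27, SE 0.18), Bmpr1a, 2.98-fold (1.58, SE 0.22), and Bend4, 6.02-fold (2.59, SE 0.35), the last 4 with adjusted p = 0.0495. A second Bend4 probe set (2.21, adjusted p = 0.0548) did not pass. Each of these 6 calls was lost without cKO replicate 1 or either Cre control, with the highest adjusted p without Cre control replicate 1 (0.299 for Gbp8 to 0.613 for Gpat3, Prok2 and Bend4). The last 4 were lost without flox control replicate 2 too, Gpat3, Prok2 and Bmpr1a without flox control replicate 3, and Gpat3 and Bend4 without cKO replicate 2. In all 10 genes passed, 7 higher and 3 lower, the others being Snord53 and 1700047M11Rik, higher, and Gm6568, lower. Of these 10, 7 also differed between the controls, each with the opposite sign: Gbp8, Emilin2, Gpat3, Prok2, Snord53, 1700047M11Rik and Gm6568. Both comparisons share the Cre control arrays, and among as many top probe sets 100 simulations of unchanged groups gave a mean overlap of 3.83 and at most 8.

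Of the lists, 7 passed against the Cre control. All 40 interferon-stimulated genes were lower (median -0.39, adjusted p = 8.5e-13, and 0.674 with an estimated correlation, and a median of -0.23 without cKO replicate 2), with Mx1 at -1.39 (SE 0.27), Mx2 at -1.37 (SE 0.31) and the immunity GTPase Iigp1 at -1.16 (SE 0.34). None passed over all genes, 13 had an unadjusted p under 0.05 by limma and 2 passed adjusted over the list alone. The LPS and NF-kB list fell here too (38 of 49 lower, median -0.27, adjusted p = 4.7e-06, and 0.674 with an estimated correlation), with the costimulatory receptor Cd40 at -0.83 (SE 0.16), Tnip3 at -1.21 (SE 0.25) and Il6 at -1.16 (SE 0.27), and 3 members passed adjusted over the list alone. The LPS and NF-kB median was -0.15 without Cre control replicate 1. HIF-1 targets other than glycolysis rose (18 of 21 higher, median 0.25, adjusted p = 0.00155, and 0.674 with an estimated correlation), with the histone demethylase Kdm3a at 0.56 (SE 0.12), and citric acid cycle genes rose (19 of 21 higher, median 0.18, adjusted p = 0.00854, and 0.674 with an estimated correlation), with Dlst at 0.45 (SE 0.15). T and NK cell markers (median -0.27, 16 of 18 lower, adjusted p = 0.00155), macrophage and monocyte markers (median -0.16, 15 of 21 lower, adjusted p = 0.0309) and apoptosis genes (median -0.17, 18 of 25 lower, adjusted p = 0.0309) fell, each with adjusted p = 0.674 with an estimated correlation. Klrk1, a receptor of NK cells, read -0.75 (SE 0.23), Apoe -0.52 (SE 0.16) and Birc2 -0.56 (SE 0.18). Adjusted over the list alone, 1 HIF-1 target and 1 T and NK marker passed and no gene of the citric acid cycle, macrophage and apoptosis lists. The apoptosis call was lost in 6 of 13 other settings: without cKO replicate 1, cKO replicate 2 (median -0.07), Cre control replicate 1 or the 2 sex-distinct pools, with no filter and with quantile scaling (adjusted p up to 0.0911), and the macrophage call without cKO replicate 3 or Cre control replicate 1 (up to 0.228). Glycolysis genes did not pass (14 of 20 higher, median 0.15, adjusted p = 0.135), with Slc16a3 at 0.81 (SE 0.24) and Pgk1 at 0.43 (SE 0.15). By limma 1885 probe sets had an unadjusted p under 0.05, and in 4823, or 34.4%, the groups did not overlap, where chance gives 20%. The count of 10 became 0 without cKO replicate 1, Cre control replicate 1 or Cre control replicate 2 (767 to 1495 probe sets at unadjusted p under 0.05 in limma), 3 without flox control replicate 2, 32 without flox control replicate 1 and 67 without cKO replicate 3.

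Arf6 was the only gene that changed the same way against each control, where independent lists would share 0.00186 genes by chance and simulated unchanged groups shared 0. Neither number can weigh this overlap, since both comparisons share the cKO arrays and unchanged groups rarely give any call at this threshold. Across probe sets, which are not independent replicates, the fold changes against the 2 controls correlated at 0.297. Simulated unchanged groups gave 0.448, since both comparisons share the cKO arrays, while the covariance, 0.0208, lay above the 0.0137 of those groups. Without cKO replicate 2 the shared count was 2. It was 0 without flox control replicate 1 or 2, cKO replicate 1, or either Cre control.

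The control groups were compared with each other to measure the background between the mouse lines. TRIM family genes on chromosome 7 were among the genes with the highest and lowest fold changes. Trim12a was 82.6-fold higher in the Cre control (log2 6.37, SE 0.57, adjusted p = 0.00518, n = 2 against 3), Trim30d 14.6-fold higher (3.87, SE 0.57, adjusted p = 0.0274) and Trim34a 5.19-fold higher (2.38, SE 0.26, adjusted p = 0.013), while Trim12c was 4.9-fold lower (-2.29, SE 0.32, adjusted p = 0.0223). Each of these 4 calls was lost without either Cre control, and those of Trim30d and Trim12c without flox control replicate 2 too (adjusted p up to 0.285). These genes lie close together, and 7 of the genes changed between the controls fell within 50 neighbouring tested genes of chromosome 7. In the cKO pools Trim12a read 11.3, 8.83 and 10.9, between the Cre controls (12.2 and 12.2) and the flox controls (mean 5.83). Of 58 genes that changed, 39 were higher and 19 lower in the Cre control. The cKO mean lay between the control means for 49 of the 58. Among probe sets this share was 86.8%, and simulated unchanged groups gave 86.1%, so choosing genes that differ between the controls can by itself give such a share. The simulated groups held no real differences, so they cannot decide what placed the cKO between the controls.

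**Figure D3:**
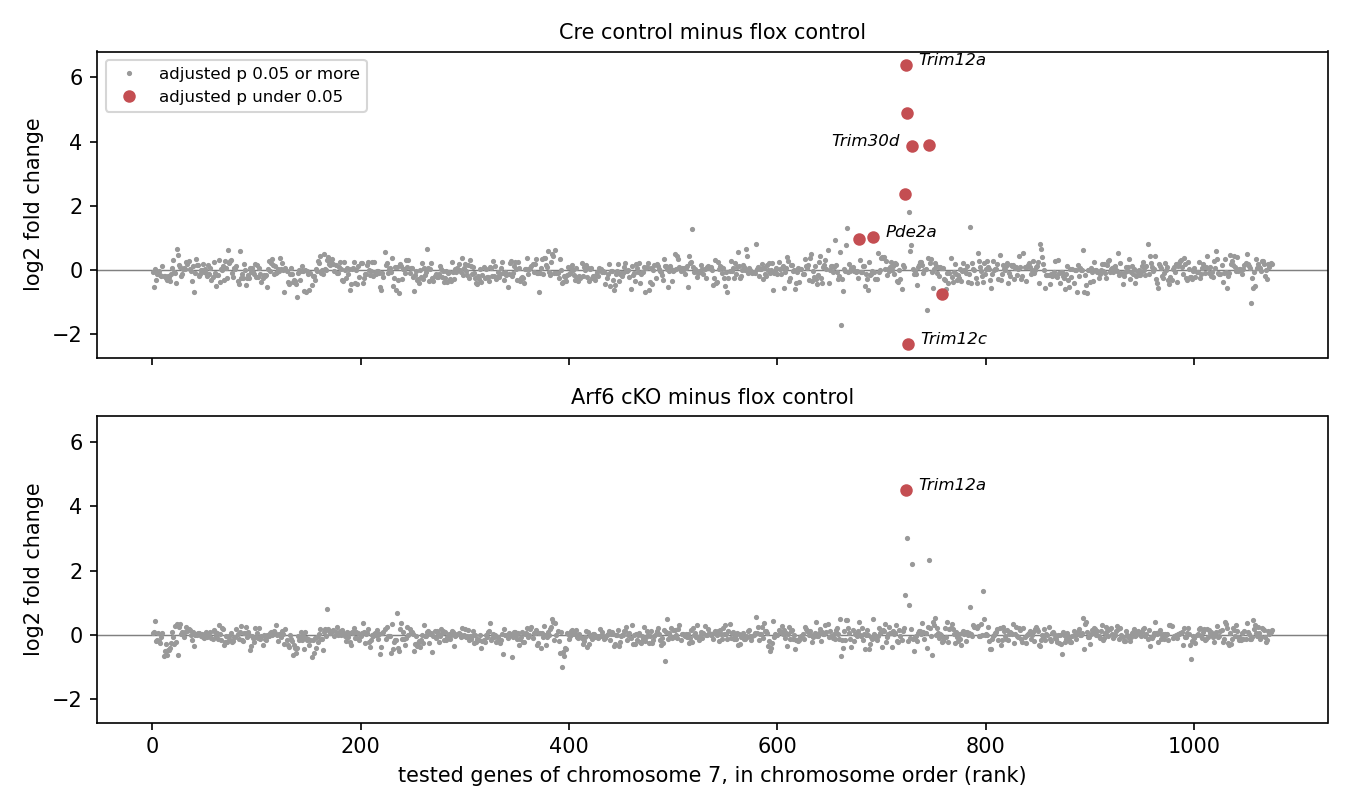
Log2 fold change (vertical axis) of the tested genes of chromosome 7 by their rank along the chromosome, for the Cre control (upper panel) and the cKO (lower panel) against the flox control, 1 point per gene, with genes past the threshold as larger points. A group of neighbouring genes stands apart in the Cre control, with Trim12a at 6.37, Trim30d at 3.87 and Trim12c at -2.29, and Trim12a is at 4.52 in the cKO.

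Other genes higher in the Cre control were Ccnyl1 (2.93, SE 0.36), Gbp8 (1.95, SE 0.21), Phf11c (1.91, SE 0.31), the antiviral GTPase Mx1 (1.64, SE 0.27), the ADP-ribosyltransferase family gene Parp11 (1.13, SE 0.19), the lymphoid and myeloid receptor Slamf7 (1.64, SE 0.22), the integrin Itga4 (1.35, SE 0.23), the costimulatory receptor Cd40 (1.04, SE 0.16) and AW046200 (1.35, SE 0.24). Lower were the matrix gene Emilin2 (-1.40, SE 0.16), the annexin Anxa3 (-1.31, SE 0.18), genes of lipid storage, Gpat3 (-1.28, SE 0.20) and the lipase inhibitor G0s2 (-0.97, SE 0.14), and the stress-response gene Sesn2 (-1.09, SE 0.19). A second G0s2 probe set (-1.15, adjusted p = 0.0815) did not pass, and a second Trim34a probe set did (1.98, adjusted p = 0.013). Further genes past the threshold on the lower side were Rps3a1 (-1.46, SE 0.19), the transglutaminase Tgm1 (-1.26, SE 0.22), Prok2 (-1.07, SE 0.18), Rabggta (-1.03, SE 0.17), the gasdermin Gsdme (-0.95, SE 0.14) and the transcription regulator Hexim1 (-0.95, SE 0.15). The adjusted p of the genes named between the controls ranged up to 0.0456. Each call named in this paragraph was lost without Cre control replicate 1 or Cre control replicate 2 (up to 0.398, for AW046200 without Cre control replicate 1). Apart from Trim34a, all but those of Gbp8, Emilin2 and Slamf7 were lost without flox control replicate 2, and all but those 3, Ccnyl1 and Rps3a1 without cKO replicate 1. Without flox control replicate 1 the calls of these 5 and of Anxa3 stayed and the others were lost, and without flox control replicate 3 those of Mx1, Parp11, Phf11c, Prok2, Sesn2 and Tgm1 were lost.

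Of the lists, 11 passed between the controls. T and NK cell markers rose in the Cre control (17 of 18 higher, median 0.56, adjusted p = 1.1e-08, and 0.0891 with an estimated correlation). Granzyme B (Gzmb) read 1.74 (SE 0.41), Klrk1 1.23 (SE 0.23), Il7r 0.88 (SE 0.16) and perforin (Prf1) 0.75 (SE 0.17), and 9 members passed adjusted over the list alone, none over all genes (11 at an unadjusted p under 0.05 by limma). Macrophage and monocyte markers (median 0.27, 16 of 21 higher, adjusted p = 0.00326, and 0.462 with an estimated correlation), dendritic cell and class II genes (median 0.35, 11 of 16 higher, adjusted p = 0.00798, and 0.462 with an estimated correlation) and interferon-stimulated genes (median 0.23, 37 of 40 higher, adjusted p = 1.65e-05, and 0.724 with an estimated correlation) rose as well. The dendritic cell median was 0.18 without flox control replicate 1 and 0.09 with no filter on dim probe sets. Specific and gelatinase granule genes fell (median -0.23, 19 of 24 lower, adjusted p = 0.00204, and 0.462 with an estimated correlation, 6 adjusted over the list alone), with Stfa3 at -1.46 (SE 0.31), and so did neutrophil core genes (median -0.12, 22 of 26 lower, adjusted p = 0.00332, and 0.442 with an estimated correlation), with Ly6g at -0.49 (SE 0.20) and the gelatinase Mmp9 at -0.38 (SE 0.12). Glycolysis genes fell (16 of 20 lower, median -0.23, adjusted p = 0.00606, and 0.462 with an estimated correlation), with the glycolytic enzymes Pgk1 at -0.60 (SE 0.15) and Ldha at -0.53 (SE 0.16) and the transporter Slc16a3 at -0.74 (SE 0.24). No glycolysis gene passed over all genes, 5 had an unadjusted p under 0.05 by limma and 1 passed adjusted over the list alone. HIF-1 targets other than glycolysis fell (17 of 21 lower, median -0.29, adjusted p = 0.000853, and 0.462 with an estimated correlation, 3 adjusted over the list alone), with Fam162a, a mitochondrial protein, at -1.01 (SE 0.19). Citric acid cycle genes (median -0.11) and endosomal recycling genes (median -0.10) fell with adjusted p = 0.0492 each (0.724 and 0.674 with an estimated correlation), with Dld at -0.45 (SE 0.14) and Rab35 at -0.66 (SE 0.16). Both calls were lost in 7 of 13 other settings, among them the omission of flox control replicate 2, cKO replicate 2, cKO replicate 3 or Cre control replicate 1, and of flox control replicate 1 for the citric acid cycle and replicate 3 for endosomal recycling (adjusted p up to 0.183 and 0.367). The citric acid cycle median was -0.07 without flox control replicate 1, and the endosomal median ranged from -0.23 without Cre control replicate 2 to -0.05 without Cre control replicate 1, and was -0.17 without flox control replicate 3. Adjusted over the list alone, 5 dendritic cell, 3 interferon-stimulated, 2 endosomal and 1 neutrophil core gene passed, and no macrophage or citric acid cycle gene. Over all genes Mx1 of the interferon list and G0s2 of the neutrophil core passed.

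**Figure D4:**
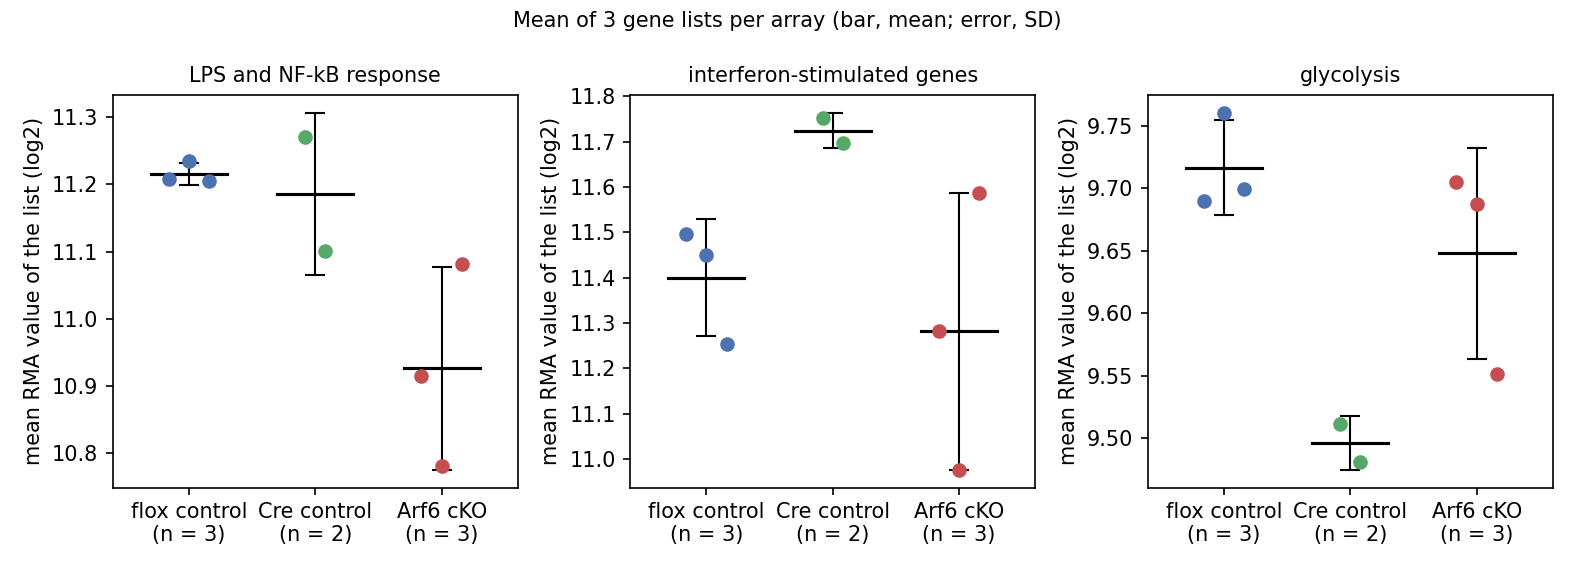
Mean level (log2) of the LPS and NF-kB response, interferon-stimulated and glycolysis gene lists in each of the 8 arrays by group, with group means as horizontal lines and SD as error bars. The LPS and NF-kB mean is 10.9 in the cKO and 11.2 in the controls, while the glycolysis mean is 9.65 in the cKO and 9.63 in the controls.

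Between the controls 2059 probe sets had an unadjusted p under 0.05 by limma, and in 4584, or 32.7%, the groups did not overlap, where chance gives 20%. The count of 68 probe sets rested on both Cre control arrays, since it became 0 without either (1158 and 1343 probe sets at unadjusted p under 0.05 in limma). It was 31 without flox control replicate 1, 18 without flox control replicate 2, 107 without flox control replicate 3, 21 without cKO replicate 1 and 235 without cKO replicate 2.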

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

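The tests in this part were chosen after the result was seen, except the counts over other splits of the genes and lists past the threshold. Among 4660 tested probe sets without a single gene symbol, which entered no gene comparison, 2 passed the threshold between the cKO and the Cre control (1 higher, 1 lower) and 17 between the controls (15 higher and 2 lower in the Cre control), a signal in data outside the main measurement. None passed in the cKO against both controls or against the flox control, with 270 and 268 at an unadjusted p under 0.05 in limma.

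Genes of chromosome 7 differed between the Cre and flox controls. Within the fullest window of 50 neighbouring tested genes 7 had changed, more than in any of 10000 random placements (at most 6, permutation p = 0.0001, the smallest they can give), consistent with a linked chromosome segment that differs between the mouse lines. The 36 interferon-stimulated genes on other chromosomes rose too, with a median of 0.25 (SE 0.08) and at most 1.64. The 5 genes of the window that rose had a median of 3.88, with and without Gm15133, whose flox control readings lay below the filter level. Those 5 were chosen because they rose, so setting the medians side by side cannot decide on a general interferon response. The Cre transgene alone is argued against, because the cKO mice are also homozygous for Cre. Yet their pools showed a median of 0.546, 0.0836 and 0.394 of the control difference on the linear scale (0.544, 0.0846 and 0.394 without Gm15133). A segment that segregates among the cKO mice may account for these unequal shares, and which strains the lines derive from was not tested.

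The LPS and NF-kB response genes were lower in the cKO against both controls at the preset correlation, a call lost with adjusted p = 0.883 with an estimated correlation and 0.643 by exact permutation. At the preset correlation a single cKO pool as the source is argued against. The list median stayed at or below -0.20 without any 1 cKO pool (camera adjusted p at most 1.8e-09). The pools were unequal, with list means of 10.92, 10.78 and 11.08 in cKO replicates 1 to 3 and at least 11.10 in the controls. Unequal sex could not be decided by leaving out the 2 pools with distinct sex-linked transcripts (median -0.26). The remaining cKO pools still read lower for Xist (7.84 and 8.51) than the remaining controls (at least 8.73). Against the flox control the markers of macrophages and monocytes did not fall (median 0.058, SE 0.06), while the list stood at -0.28. Against the Cre control the markers fell too (-0.16, SE 0.07, against -0.27, a gap of 0.11 with 0.21 for 2 standard errors). These SE are over genes, which are not independent, and hold no spread between pools. Fewer macrophages and monocytes in the cKO pools was therefore not excluded for either control. A weaker LPS response in neutrophils without Arf6 stays open as a hypothesis, as do differences in the timing or dose of LPS between pools, which were not tested. The test that counted lists over other splits did not exclude chance, since 52 of 56 splits gave at least 3 lists, up to 12. Structure among the arrays other than the groups, or a preset correlation too low for these lists, could give such counts. No test told these apart, and with an estimated correlation no list passed in any comparison.

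T and NK cell markers were higher in the Cre controls (median 0.56). More T and NK cells in the Cre control pools may account for it, with 17 of 18 members higher, including all 7 cytotoxic genes (median 0.75) and 10 of 11 other T cell genes (median 0.27). A lower neutrophil share cannot be told apart from it: of the 2 lists of abundant markers the lower, macrophages and monocytes, had a median of 0.27 (SE 0.07), a gap of 0.29 to the T and NK list against 0.33 for 2 standard errors, and neutrophil core genes fell (-0.12). None of the lists of dimmer markers of other cell types passed. Eosinophils stood at 0.46 (SE 0.21, over genes and not pools, as for the other lists), and the others lay within their SE of 0. These were endothelium at 0.13 (SE 0.16), B cells at -0.0037 (SE 0.17) and fibroblasts at -0.06 (SE 0.07). Keratinocytes stood at -0.01 (SE 0.06) and erythroid cells and platelets at -0.02 (SE 0.11). Of the T and NK markers 2 are held by another list, 7 lay above the median level and the most abundant, Gzmb, averaged 8.90, although negative selection would remove most such cells, and expression by the neutrophils themselves was not tested.

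For the cKO against both controls, with the 5 controls as 1 group, the real split gave 1 gene, the targeted Arf6 itself. Of 56 splits 2 gave as many, the real one and cKO replicate 3 with both Cre controls. The lowest adjusted p by limma was 0.00896 in the real split and 0.00668 in the other. A count that rests on the deleted gene and is tied by another grouping cannot decide whether chance accounts for it. The 610 probe sets in which all cKO arrays lay beyond all controls were matched or passed by 17 of 56 splits, the highest with 1190, so chance cannot be excluded there. Against the flox control the real split gave 6 probe sets, matched by 1 of 10 splits (itself), and the highest other gave 0, but 10 splits are too few for a share under 0.05.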

How the results depend on the processing

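The settings that left out the 2 pools with distinct sex-linked transcripts, left out the genes of the chromosome 7 window, used identical probe sets once or centred arrays for the lists, and all alternatives of the lists against each control alone, were chosen after seeing the data. The genes followed through up to 19 settings were 12 against both controls, 12 against the flox control, 7 against the Cre control and 25 between the controls. None of them turned its direction. Genes named only as members of a list were not followed singly. Against both controls, Arf6 stayed at a log2 fold change of -1.79 to -1.58 without any 1 array. There it lost its call without flox control replicate 2, Cre control replicate 1 or Cre control replicate 2 (adjusted p = 0.0773, 0.154 and 0.182) and, at -1.75, without the sex-distinct pools (adjusted p = 0.0791), where fewer arrays carried the test. The counts of probe sets past the threshold were 1 for the cKO against both controls, 6 against the flox control, 10 against the Cre control, 68 between the controls and 1 changed the same way against each control. With array weights they became 13, 12, 145, 819 and 5. Without the sex-distinct pools they became 0, 0, 4, 24 and 0. With an unadjusted p under 0.01 and a 1.5-fold change the first 4 were 164, 172, 430 and 517. A fit of the compared groups alone gave 0 against the flox control, 5 against the Cre control, 131 between the controls and 0 the same way. With 1 probe set per gene, or identical probe sets used once, 3 remained against the flox control. Against the Cre control, 5 passed with no filter on dim probe sets and 16 with an intensity trend and robust prior. Leaving out each array in turn gave 0 to 31, 0 to 11, 0 to 67, 0 to 235 and 0 to 2, where a group left with 1 array is assumed to vary like the others. The highest of these came without cKO replicate 3 (31 and 67) or cKO replicate 2 (11, 235 and 2). Where limma called 0, between 704 and 1495 probe sets had an unadjusted p under 0.05. Lists past the threshold numbered 3, 5, 7 and 11 and became 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 2 with fry. Against both controls they were 6 with no filter, and against the flox control 3 with quantile normalization and 2 without the sex-distinct pools. Leaving out each array gave 2 to 6, 4 to 7, 5 to 9 and 8 to 14 lists. The LPS and NF-kB list passed in 13 of 13 other settings at the preset correlation in each cKO comparison. Beyond the smaller number of arrays or genes tested, the cause of these shifts was not tested. No paired analysis was possible because the pools of different genotypes are separate mice with no labelled pairing. Dim probe sets, whose signal lies near background, and probe sets near the highest readings limit what small changes can be seen.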

Other observations

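No test in this part was chosen after the result was seen, apart from the choice of which values to give. The lists that did not pass against both controls numbered 33, with medians from -0.06 (endothelial markers) to 0.17 (eosinophil markers). Genes of energy metabolism lay slightly above 0: HIF-1 targets 0.08, glycogen metabolism 0.08, the pentose phosphate pathway 0.09, the citric acid cycle 0.11 (17 of 21 higher, adjusted p = 0.0746) and fatty acid oxidation 0.08. Azurophil granule genes were higher in 12 of 12 members (median 0.09, adjusted p = 0.0824), while specific and gelatinase granule genes had a median of 0.00 and NADPH oxidase genes 0.03. For the machinery around Arf6, the other ARF and ARL GTPases had a median of 0.02, ARF6 exchange factors, GAPs and effectors 0.06 and endosomal recycling 0.04. Receptor lists lay close to 0, with the TLR4 complex at -0.00, chemoattractant receptors at 0.05, integrins and adhesion at 0.05 and Fc and complement receptors at 0.05.

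Of the genes in these 33 lists 5 passed adjusted over their own list alone. They were Olfm4, a protein of a subset of neutrophil granules (0.55, SE 0.11), the chemerin receptor Cmklr1 (0.52, SE 0.14) and Sesn2 (0.80, SE 0.15), higher, and the complement receptor C5ar2 (-0.51, SE 0.13) and the platelet collagen receptor Gp6 (-0.87, SE 0.18), lower. None passed over all genes, with an adjusted p of at least 0.239 in limma.

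The remaining lists had medians of 0.03 for the unfolded protein and integrated stress response, -0.03 for heat shock and immediate early genes, -0.01 for the cell cycle, -0.04 for early neutrophil precursors and 0.02 for ribosomal proteins. Marker lists gave -0.00 for macrophages and monocytes, 0.12 for dendritic cells, 0.08 for B cells, -0.00 for T and NK cells, 0.14 for fibroblasts, 0.04 for erythroid cells and platelets and 0.05 for keratinocytes. For every list past the threshold in any comparison the median, the mean and the test had the same sign, while against both controls 8 lists that did not pass differed in sign between them. The mast cell and basophil list had 4 tested members and was not tested as a set.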
